A study of Homo sapiens with 24 samples.

How the data were processed

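Total RNA of MDA-MB-231 cells that stably express the wild-type oestrogen receptor alpha or its DBDmut form was hybridised as biotin-labelled cRNA to Affymetrix arrays, 1 array per sample. Per the labels' protocols, cells were kept in phenol-red free medium with stripped serum, insulin, glutathione and hydrocortisone, a glucocorticoid, and were treated with 10 nM estradiol. The deposited values are log2 intensities made by the authors with GCRMA, which corrects background, normalizes between arrays and summarises probes per probe set, per the submitters' processing notes; its version is not given in the sources used here. The labels do not state the base of the logarithm. It was taken as 2, since the highest value would exceed the 16-bit range of a scanner with a natural or base 10 logarithm. No step was applied to these values except where an alternative says so. Background correction of this kind compresses values near the floor, so that changes of weakly expressed genes are imprecise.

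Gene names came from a table that pairs the platform's probe sets with genes, updated by gene identifier through a human gene table whose assembly is GRCh38.p14 and which was used for names only. Of the probe sets, 19071 had 1 symbol, 1043 had several and 2169 had none; 19059 of the first matched a current symbol and 12 did not. Each of 11963 genes was represented by its probe set with the highest mean. Genes with a log2 value of 5 or more on at least 2 arrays were tested, 5575 in all. Arrays were grouped by line and time as labelled, in 12 groups of 2, and the 24 columns were all used.

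A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend of the spread on mean level), leaving 12 residual degrees of freedom. Contrasts were each time against 0 h within a line, the difference of these changes between lines (WT minus DBDmut), and DBDmut minus WT at 0 h. Genes changed at any time were found with the moderated F test over the 5 times. Tests were adjusted by Benjamini-Hochberg at 0.05 over the tested genes, within each contrast or F test. Values are log2 changes with the standard error of the model. With 2 arrays per group no exact test of a single gene can pass the threshold, so every p of a gene is from limma. Changes were correlated between lines across genes without a p.

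The 19 gene lists covered classical oestrogen-induced, immediate early, AP-1 linked protease, NF-kB, replication, mitosis, growth arrest, TGF-beta, RUNX, lipid synthesis, unfolded protein, glucocorticoid, ribosome biogenesis, interferon, hypoxia, epithelial and mesenchymal genes, with markers of luminal breast lines and of fibroblasts. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; DUSP1, MYC and NFKBIA are each in more than 1 list. Members were also counted with p values adjusted over the list alone. The groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall per line, among those called at any time and at 1 time at least, with treated arrays on one side of both 0 h arrays at the time of the largest change. It took 10 per direction for the response difference and for the line difference, and members of each list with the largest changes. The rule and the list tests were applied again without the array labelled WT 24 h A, a choice made after its position was seen. Other genes given as values were chosen as examples after they were seen.

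The position of an array between the lines was its median over genes, those that separate the other WT arrays from the DBDmut arrays by 1.5 log2 units or more, of its value scaled between their means. No pair of arrays was identical (0 pairs). The steps were tested on simulated data with 200 changed genes among 5575. The simulated noise was independent between genes and arrays, with no deviating array and no effect shared by arrays of different groups. The rates given next may therefore not hold for the real arrays. For WT at 8 h, 14%, 60%, 96% and 98% of genes changed by 0.5, 1, 2 and 3 log2 units were called, with 3 false calls in 137, and for DBDmut at 24 h 10%, 58%, 96% and 98%, with 6 in 137. Alternatives were no filter and a filter at 7, quantile normalization, no trend, the mean of a gene's probe sets, each probe set on its own, a replicate block, the arrays of 1 line alone, each array left out in turn, and a line difference averaged over times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets with no symbol or several were not analysed here by gene.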

Results

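Gene expression was measured in MDA-MB-231 cells, a human breast cancer line that lacks its own oestrogen receptor, after stable expression of either the wild-type oestrogen receptor alpha (WT) or a form named for a mutated DNA-binding domain (DBDmut). Cells of each line were exposed to 10 nM estradiol (E2), the natural ligand of the receptor, and RNA was taken at 0, 1, 2, 4, 8 and 24 h. Each of the 12 combinations of line and time had 2 arrays, 24 in all. The median log2 value per array lay between 3.21 and 3.45, and between 4960 and 5284 of all 11963 genes reached a log2 value of 5 on an array. The number of arrays limits the precision of every value below. The design asks which E2 responses need the receptor's contact with DNA, by comparing the time course of each line with its own 0 h arrays and the courses with each other. No array of a later time without E2 is among these samples, so hormone and time in culture cannot be told apart, nor can the receptor form and the line that carries it. The labels do not say whether the arrays of a group come from separate cultures, so replicates may be technical.

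The array labelled WT 24 h A stood with the arrays of the other line. On a scale where the mean of the other WT arrays is 0 and that of the DBDmut arrays is 1, its median position over 212 genes that separate the lines was 0.957, against -0.101 to 0.129 for the other arrays labelled WT and 0.914 to 1.07 for the arrays labelled DBDmut. TFF1 read 2.60 on this array and 12.03 on its partner WT 24 h B, and TGFBI, which reached 10.93 in the DBDmut 24 h group, read 5.14. Across tested genes its correlation was 0.90 with that partner and 0.994 with the mean of the DBDmut 0 h arrays. The label was kept, so results with all 24 arrays come first and results without this array, a setting chosen after its position was seen, stand beside them. In that second setting the WT 24 h group is the array WT 24 h B alone, which is assumed to vary like the other groups. The array labelled WT 1 h A also lay apart. Its correlation with its partner was 0.941, against 0.982 to 0.992 in the pairs of the other groups, with WT 24 h left out. The 3' minus 5' difference of the control probe sets, a sign of RNA quality, ranged from 0.58 to 1.97 for ACTB and from 0.05 to 0.99 for GAPDH, highest on WT 4 h A for both.

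**Figure D1:**
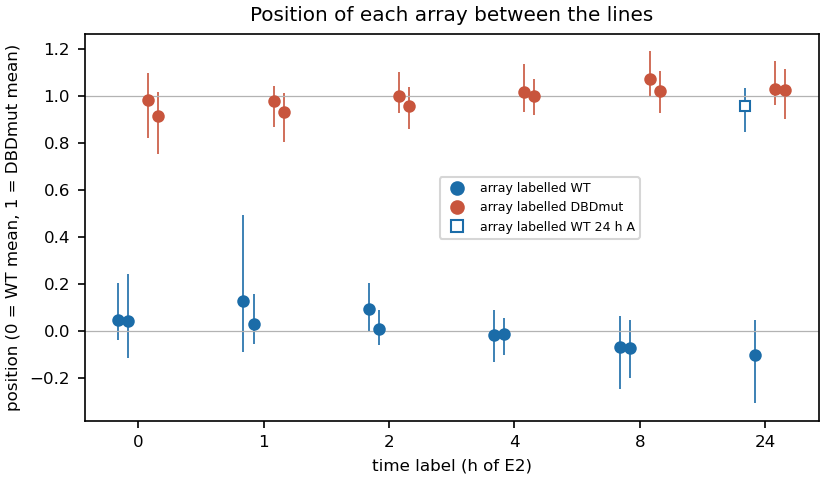
Position of each array between the lines, over genes that separate them, by time label; points are medians over genes and bars run from the lower to the upper quartile. The open square, the array labelled WT 24 h A, lies at 0.957, while the other arrays labelled WT lie between -0.101 and 0.129.

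ESR1, the gene of the receptor, was strongly detected in both lines and higher in DBDmut. The probe set with the highest mean averaged 11.04 ± 0.35 (SD, n = 11, without the array labelled WT 24 h A) in WT and 11.82 ± 0.19 (SD, n = 12) in DBDmut, and read 12.06 on the array labelled WT 24 h A. At 0 h the difference was 0.72 ± 0.22 log2 units (SE, limma adjusted p = 0.0358). Those means pool times, and without the array labelled WT 24 h A ESR1 changed in WT at 4 h, by -0.81 ± 0.15 (adjusted p = 0.00885, against 0.255 with all arrays), where DBDmut gave -0.52 ± 0.15 (adjusted p = 0.116). On the probe set with the highest mean, WT 4 h A read 10.39 and WT 4 h B 10.69, against 11.38 and 11.32 on the WT 0 h arrays. WT 4 h A was highest in the RNA quality check above, so the size of that fall is uncertain. Another ESR1 probe set stayed near background in both lines, at 2.09 and 2.13. These probe sets measure the transcript and cannot show which form of the receptor it encodes.

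In the WT line, E2 exposure was followed by rises of PITX1, MXD1 and TIMP3 and by early falls of KLF6, DUSP5 and TRIB1. PITX1, a homeobox transcription factor, rose by 3.67 ± 0.59 log2 units at 8 h (SE, n = 2 against 2, adjusted p = 0.0228), and MXD1, an antagonist of MYC, rose by 3.29 ± 0.47 at 2 h (adjusted p = 0.00396). TIMP3, an inhibitor of matrix metalloproteinases, rose by 2.40 ± 0.31 at 8 h (adjusted p = 0.00436). KLF6 and DUSP5, an early response transcription factor and a phosphatase of the MAP kinase ERK, changed by -1.83 and -1.61 at 2 h (adjusted p = 1.2e-04 and 9.6e-05). Smaller rises were called for GADD45B (1.33 at 1 h), CEBPB (1.32 at 2 h), the amino acid transporter SLC7A5 (1.30 at 8 h), ARRB1 (1.27 at 8 h) and DUSP7 (1.23 at 2 h). Further rises were BMERB1 (1.22 at 24 h), SLCO4A1 (1.14 at 2 h), ALDH3A2 (0.87 at 8 h) and RGS10 (0.65 at 4 h). Falls were called for TRIB1 (-1.85), GADD45A (-1.40), TGIF1 (-1.33), ADM (-1.08) and JUN (-1.01) at 2 h. Later falls were those of DUSP10 at 4 h (-1.74), LTBP2 (-1.73), PPRC1 (-1.17) and ADORA2B (-0.85) at 8 h, and PRSS3 at 24 h (-0.95), whose probe set may be shared with other trypsinogen genes. Of 5575 genes tested, 50 changed at any time (23 higher, 27 lower, moderated F test of limma), and 3, 15, 9, 20 and 5 genes were called at 1, 2, 4, 8 and 24 h. A named gene passed the any-time test, and its value is that of the time with the largest change. The counts that follow all include the array labelled WT 24 h A, which lay with the DBDmut arrays. The any-time count was 4 without the array WT 0 h A, 0 by limma in the 12 arrays of the line alone (250 at an unadjusted p under 0.05), and 978 without WT 24 h B.

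Without the array labelled WT 24 h A, the number of genes called in WT at any time was 407 (230 higher, 177 lower), among them 48 of the 50, and the counts at 1, 2, 4, 8 and 24 h were 10, 51, 71, 292 and 243. The largest rise then was that of TFF1, a secreted trefoil peptide and a classical E2 target: 3.32 ± 0.50 at 4 h, 5.68 ± 0.50 at 8 h and 6.95 ± 0.61 at 24 h (adjusted p = 1.0e-03, 2.3e-06 and 5.0e-06). With all arrays the 8 h value was the same, 5.68, but with a larger SE of 1.71 (adjusted p = 0.142). SERPINA1, which encodes the protease inhibitor alpha-1-antitrypsin, rose by 3.85 ± 0.50 at 8 h, and INHBB, a subunit of activin and inhibin B, by 3.56 ± 0.23 (adjusted p = 1.6e-04 and 2.5e-07). At 24 h, on 1 array, the largest other rises were those of DEFB1 (4.56), TGM2 (4.43), COL18A1 (3.89), the epithelial keratin KRT19 (3.67), OLFML3 (3.51), the complement component C3 (3.48), CRISPLD2 (3.44) and CST1 (3.43), which is near-identical to CST4. Genes that then joined the falls were TNFAIP3 (-1.91 at 1 h, any-time adjusted p = 0.0262), GCNT2 (-1.58 at 4 h), the chemokine gene CCL2 (-1.51 at 4 h), NLE1 (2.82-fold at 8 h) and, at 24 h, NDC1 (-1.62), TWNK (-1.57) and PLAU (-1.57), the urokinase gene. Leaving out the partner WT 24 h B in place of A also raised the counts, to 978 genes at any time and 794 at 24 h, and turned the 24 h value of TFF1 to -2.48, so the choice between the arrays rests on the position of A among the lines and not on the counts.

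**Figure D2:**
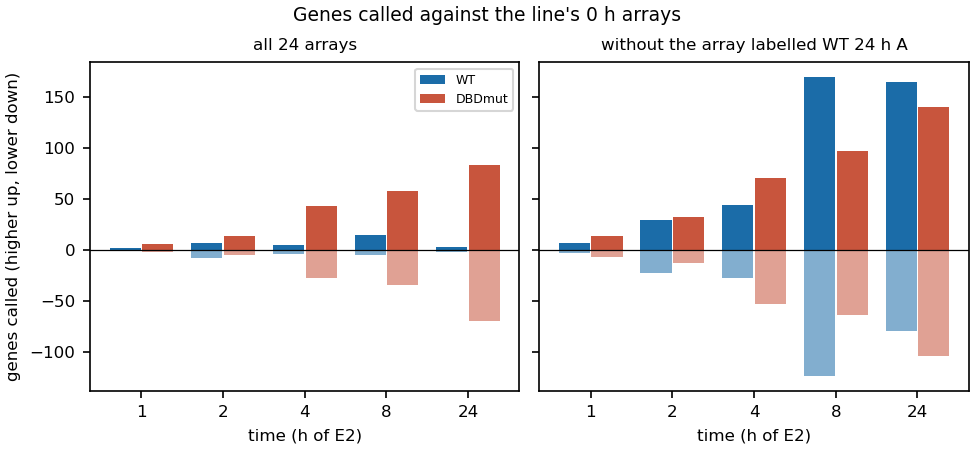
Number of genes called at each time against the line's own 0 h arrays (limma, Benjamini-Hochberg 0.05), with higher genes above 0 and lower genes below. With all arrays, 20 WT and 92 DBDmut genes were called at 8 h, and without the array labelled WT 24 h A, 292 and 160.

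**Figure D3:**
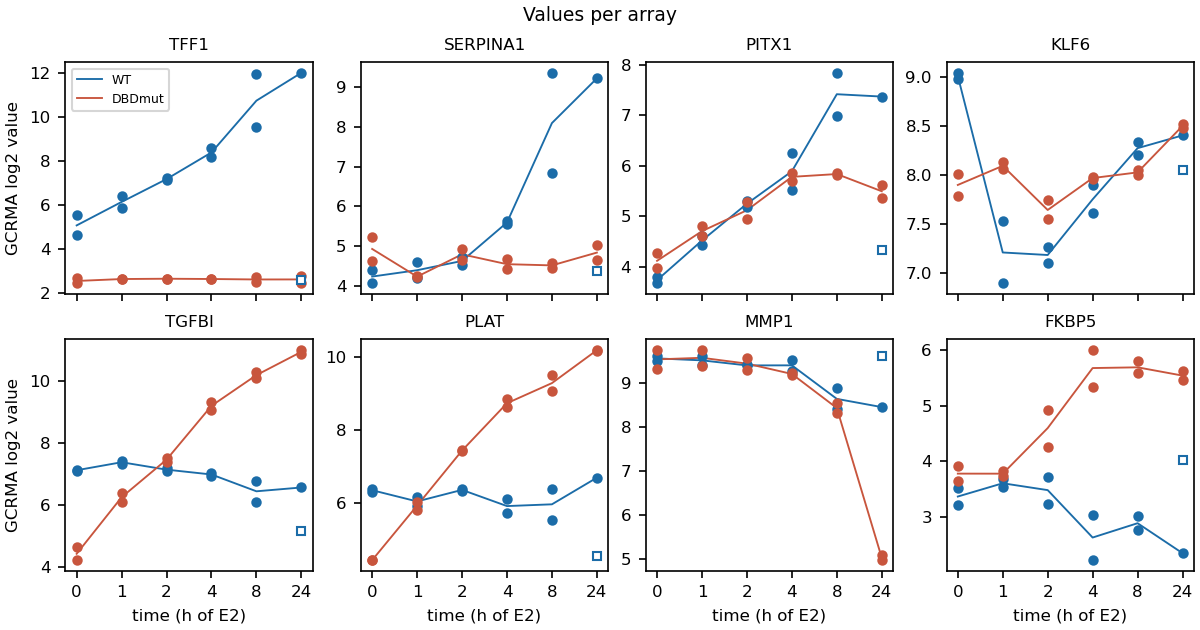
GCRMA log2 value of 8 genes on every array by time; points are arrays, lines join group means without the array labelled WT 24 h A, which is drawn as an open square. TFF1 reached 12.03 on WT 24 h B and TGFBI a mean of 10.93 in the DBDmut 24 h group.

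Among gene lists fixed before the data were examined, the classical oestrogen-induced genes went up in camera in WT at 8 h (median 0.79, adjusted p = 3.0e-06, and adjusted p = 0.0598 with an estimated correlation). Of 13 tested members, 1 rose, 0 fell and 12 were not called (3 called when adjusted over the list alone), the rise being that of SLC7A5. Without the array labelled WT 24 h A 7 rose, 1 fell and 5 were not called (10 adjusted over the list alone). Besides TFF1 and SERPINA1, the aspartyl protease gene CTSD (1.45), IGFBP4 (1.34) and TIPARP (1.05) rose at 24 h in that setting, while MYC fell by 0.91 at 2 h. Without the array the list's values at 8 h were adjusted p = 1.1e-07 and adjusted p = 0.00799 with an estimated correlation. Immediate early genes, the first genes switched on by growth signals, fell as a list at 2 h, with a median of -0.35 (adjusted p = 4.0e-06, and adjusted p = 0.0412 with an estimated correlation). Of 20 members, 1 rose, 3 fell and 16 were not called (15 adjusted over the list alone), the falls being KLF6, DUSP5 and JUN, while without the array labelled WT 24 h A 5 rose and 7 fell.

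Ribosome biogenesis, DNA replication and mitosis genes went down in camera in WT at 8 h, calls that an estimated correlation ended. Without the array labelled WT 24 h A it still ended those of DNA replication (adjusted p = 0.309 at 8 h and 0.254 at 24 h with an estimated correlation) and mitosis genes (adjusted p = 0.603 and 0.284 with an estimated correlation). Ribosome biogenesis genes had a median of -0.52 at 8 h (camera adjusted p = 4.0e-09, adjusted p = 0.192 with an estimated correlation). With that array left out the latter was adjusted p = 0.00224 with an estimated correlation. Of 19 members 0 rose, 2 fell and 17 were not called (6 adjusted over the list alone), with MRTO4 at -1.06 and NIP7 at -0.89 at 8 h. With that array left out 0 rose, 8 fell and 11 were not called. DNA replication and G1/S genes had a median of -0.42 at 8 h (adjusted p = 3.0e-08, adjusted p = 0.419 with an estimated correlation). Of 31 members 0 were called by limma with all arrays (6 at an unadjusted p under 0.05, 1 adjusted over the list alone). Without the array 0 rose, 4 fell and 27 were not called, with GINS2 at -1.18 and PRIM1 at -0.91 at 24 h. Mitosis and G2/M genes had a median of -0.26 at 8 h (adjusted p = 0.0108, adjusted p = 0.769 with an estimated correlation). Of 32 members 0 were called by limma with all arrays (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). UBE2C, CDC20 and AURKB fell without the array. Without WT 8 h A the mitosis list's direction in camera at 8 h turned (adjusted p = 0.574). Growth arrest genes went up at 8 h (median 0.17, adjusted p = 0.0175, adjusted p = 0.631 with an estimated correlation). Of 16 members 2 rose, 1 fell and 13 were not called (4 adjusted over the list alone), the rises being MXD1 and GADD45B and the fall GADD45A, while without the array labelled WT 24 h A 5 rose and 1 fell. TGF-beta pathway genes went down at 4 h (median -0.35, adjusted p = 2.1e-04, adjusted p = 0.220 with an estimated correlation), a time whose array WT 4 h A was highest in the RNA quality check above. LTBP2, TGIF1 and SMAD3 fell among 14 members, with no rise (7 adjusted over the list alone), while without the array labelled WT 24 h A 2 rose and 5 fell. Epithelial genes (7 members, 0 called by limma, 3 at an unadjusted p under 0.05, 1 adjusted over the list alone) and AP-1 linked protease genes (11 members, 1 rise, TIMP3, 5 adjusted over the list alone) went down at 4 h with medians of -0.43 and -0.15 (adjusted p = 0.00710 and 0.0280, adjusted p = 0.123 and 0.192 with an estimated correlation). With that array left out 1 rose and 0 fell of the epithelial and 1 rose and 4 fell of the AP-1 linked protease genes.

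In the DBDmut line, E2 exposure was followed by large rises of TGFBI, PLAT, SLC26A2 and RHOB and by a large fall of MMP1. TGFBI, a secreted matrix protein induced by TGF-beta, rose by 6.52 ± 0.32 log2 units at 24 h (SE, n = 2 against 2, adjusted p = 2.3e-09), after 3.04 at 2 h and 5.77 at 8 h. PLAT, tissue plasminogen activator, rose by 5.75 ± 0.44 and the sulfate transporter gene SLC26A2 by 5.50 ± 0.66 (adjusted p = 2.2e-07 and 5.5e-05). RHOB, a small GTPase, had its largest change at 4 h (5.04 ± 0.77, adjusted p = 0.00125), and in WT it also gave a rise, of 1.65 at 8 h. MMP1, interstitial collagenase, changed by -4.50 ± 0.28 at 24 h (adjusted p = 2.3e-08). At 8 h its change was -1.10 in DBDmut and -0.92 in WT. Other rises at 24 h were those of AKR1C1 (4.57) and AKR1C2 (4.14), steroid-metabolising reductases so alike that their probe sets may not tell them apart. So were those of NNMT (4.48), HEG1 (3.98) and AKAP12 (3.83), and of the chemokine genes CXCL8 (4.37) and CXCL2 (3.85). CXCL8 rose from a lower level than in WT, with a 0 h difference of -3.64 ± 0.94 (DBDmut minus WT, limma adjusted p = 0.0183). For CXCL2 that difference was -1.55 (adjusted p = 0.147). PTGES, a prostaglandin E synthase, rose by 3.73 at 8 h. Falls at 24 h were called for TRIB2 (-3.39), SERPIND1 (-3.17), LTBP1 (-2.76), steroid sulfatase STS (-2.60), the lymphatic growth factor VEGFC (-2.37), TSC22D1 (-2.29), MARCKSL1 (-2.13) and the Notch ligand JAG1 (3.99-fold). At 8 h falls were called for IL1B (-2.25), IER3 (-2.10) and SIGLEC15 (-1.93). In all 150 genes changed at any time (78 higher, 72 lower), and 8, 19, 70, 92 and 152 genes were called at 1, 2, 4, 8 and 24 h. Without the array labelled WT 24 h A, which enters here only through the shared estimate of the spread, 234 genes changed (120 higher, 114 lower), including all 150, and the counts per time were 21, 45, 123, 160 and 244. The any-time count was 96 without the array DBDmut 24 h B.

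Glucocorticoid response genes, a list of targets of the related glucocorticoid receptor, went up in camera in DBDmut at 2 h (median 0.27, adjusted p = 9.1e-05, adjusted p = 0.221 with an estimated correlation) and at each later time. Their median was 0.45 at 4 h, 0.52 at 8 h and 0.88 at 24 h (adjusted p = 1.5e-05, 1.3e-05 and 2.0e-07, adjusted p = 0.162, 0.162 and 0.124 with an estimated correlation). Without the array labelled WT 24 h A the 24 h value was adjusted p = 0.0213 with an estimated correlation. Of 12 members 6 rose, 0 fell and 6 were not called (7 adjusted over the list alone), led by the phosphatase gene DUSP1 (2.40 at 24 h), CEBPD (1.94 at 24 h) and FKBP5, a co-chaperone of steroid receptors (1.91 at 8 h). The list also went up in WT, with a median of 0.36 at 8 h (adjusted p = 0.00183, adjusted p = 0.331 with an estimated correlation). There 0 members were called by limma with all arrays (7 at an unadjusted p under 0.05, 4 adjusted over the list alone). Without the array the WT list had a median of 0.54 at 24 h (adjusted p = 9.0e-07, adjusted p = 0.0180 with an estimated correlation), and adjusted p = 0.0327 and 0.0327 with an estimated correlation at 2 and 8 h. Of its members 6 then rose, CRISPLD2, SGK1, ANGPTL4, CEBPD, DUSP1 and NFKBIA. NF-kB and cytokine genes in DBDmut went down at 2 h (median -0.31, adjusted p = 0.00360, adjusted p = 0.898 with an estimated correlation). They went up at 24 h (median 1.42, adjusted p = 3.5e-06, adjusted p = 0.244 with an estimated correlation). Of 15 members 8 rose, 1 fell and 6 were not called (11 adjusted over the list alone), the rises including CXCL8, CXCL2, CCL20 (3.29) and CXCL3 (2.98) and the fall being IL1B. In WT 0 members were called by limma (4 at an unadjusted p under 0.05, 1 adjusted over the list alone), or 5 rises and 3 falls without the array. The list then also went up in WT at 24 h (median 0.93, adjusted p = 0.00134, adjusted p = 0.308 with an estimated correlation). AP-1 linked protease and invasion genes went down at 24 h (median -0.59, adjusted p = 4.0e-04, adjusted p = 0.0800 with an estimated correlation). MMP1, HBEGF (-1.76 at 4 h) and PLAUR (-1.37), the urokinase receptor, fell and PLAT rose among 11 members (7 adjusted over the list alone). Immediate early genes went down at 4 h (median -0.14, adjusted p = 5.9e-04, adjusted p = 0.124 with an estimated correlation). Of 20 members 3 rose, 4 fell and 13 were not called (15 adjusted over the list alone), among them falls of IER3 and CCN2 (-1.85 at 2 h) and a late rise of DUSP6 (1.93), while without the array labelled WT 24 h A 6 rose and 7 fell. Classical oestrogen-induced genes had no list call in DBDmut and 0 of 13 members called by limma (3 at an unadjusted p under 0.05), or 2 rises, TIPARP and MYC, without the array labelled WT 24 h A. DNA replication, mitosis and ribosome biogenesis genes had no list call and 0 members called in DBDmut in either setting (with all arrays 0, 0 and 0 members at an unadjusted p under 0.05).

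**Figure D4:**
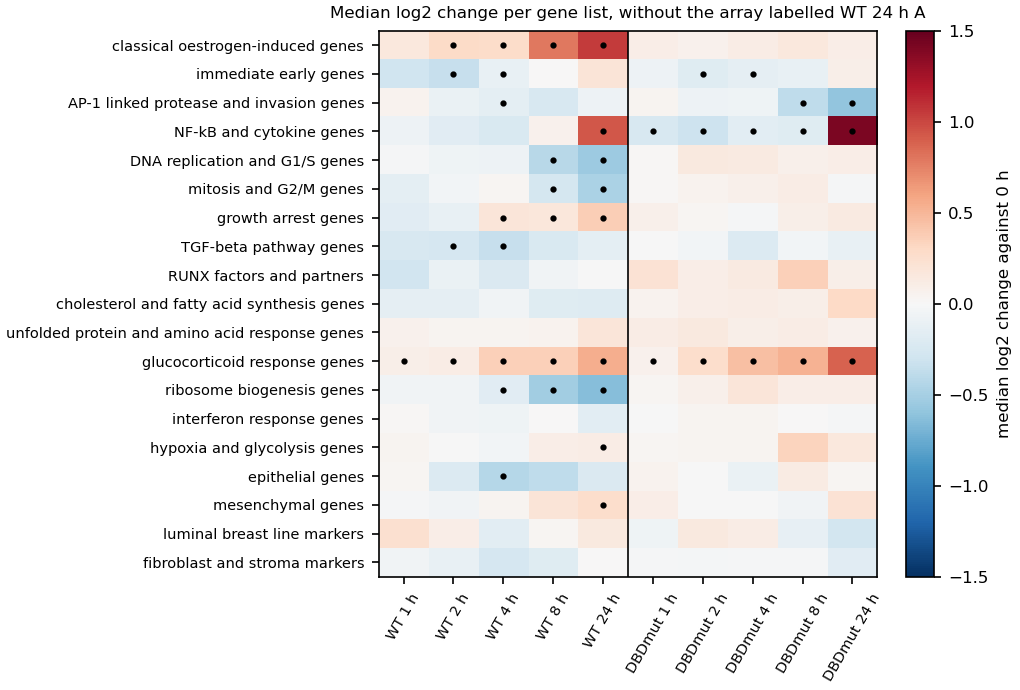
Median log2 change of the tested members of each fixed gene list against the line's 0 h arrays, without the array labelled WT 24 h A; dots mark lists past 0.05 in camera with its preset correlation. The classical oestrogen-induced genes reach 0.79 in WT at 8 h, and the NF-kB and cytokine genes 1.42 in DBDmut at 24 h.

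The responses of the lines differed for 114 genes at any time (51 with the higher change in WT and 63 in DBDmut, F test of the interaction), for 47 at 8 h and for 99 at 24 h. TGFBI had the largest difference, -7.78 ± 0.45 for WT minus DBDmut at 24 h (adjusted p = 3.4e-08), followed by PLAT (-6.48 ± 0.62) and SLC26A2 (-6.45 ± 0.94). These were, without the array labelled WT 24 h A, -7.07, -5.41 and -5.42. Differences toward DBDmut were also called for CXCL8 (-5.84), AKR1C1 (-4.36), TNFAIP3 (-4.32) and AKR1C2 (-4.12) at 24 h, AKAP12 (-4.35) and PTGES (-3.80) at 8 h, and SHROOM2 (-4.05) at 4 h. Without that array CXCL8 gave -3.42 and TNFAIP3 -3.43. Toward WT, ZMIZ1, a transcriptional co-regulator, differed by 4.34 ± 0.92 at 8 h, TRIB2 by 4.25 ± 0.62 and MMP1 by 3.97 ± 0.39 at 24 h (adjusted p = 0.0317, 0.00100 and 1.3e-05). MXD1 (3.28 at 2 h), EGR1 (3.03 at 4 h), SERPIND1 (2.79 at 24 h), STS (2.71 at 24 h), the peroxisomal oxidase gene ACOX2 (2.66 at 24 h), IER3 (2.64 at 8 h) and P3H2 (2.63 at 24 h) completed the named genes. Ribosome biogenesis genes had a lower change in WT at 8 h (median difference -0.67, camera adjusted p = 3.0e-05, adjusted p = 0.891 with an estimated correlation). Their median was, without the array labelled WT 24 h A, -0.67 at 8 h and -0.71 at 24 h (adjusted p = 4.7e-06 and 2.9e-05, adjusted p = 0.0147 and 0.0147 with an estimated correlation). DNA replication and G1/S genes also had a lower change in WT at 8 h (median -0.51, adjusted p = 3.4e-04, adjusted p = 0.891 with an estimated correlation). Classical oestrogen-induced genes had a higher change (median 0.30, adjusted p = 0.00523, adjusted p = 0.571 with an estimated correlation). At 24 h the differences of AP-1 linked protease (median 0.83), NF-kB (-0.97) and glucocorticoid response genes passed in camera (adjusted p = 0.00665, 0.0181 and 0.0183, adjusted p = 0.237, 0.891 and 0.891 with an estimated correlation). The difference of glucocorticoid genes had an adjusted p of 0.348, and that of NF-kB genes 0.0820, without the array labelled WT 24 h A. The median difference over all tested genes was -0.12 at 8 h and -0.17 at 24 h. Without the array labelled WT 24 h A, 300 genes differed at any time, 112 of the 114 among them, 224 at 8 h and 265 at 24 h. Of these 155 had the higher change in WT and 145 in DBDmut at any time. The split was 112 and 112 at 8 h, against 14 and 33 with all arrays, and 149 and 116 at 24 h, against 38 and 61, so that the lean at 24 h turned. Classical oestrogen-induced genes also had a higher change in WT at 24 h in that setting (adjusted p = 0.00329, adjusted p = 0.134 with an estimated correlation). DNA replication and mitosis genes had a lower one (adjusted p = 4.7e-06 and 0.00546, adjusted p = 0.835 and 0.864 with an estimated correlation). TFF1 then had the largest difference toward WT (6.88 ± 0.79 at 24 h, adjusted p = 4.1e-05), followed by SERPINA1 (5.06) and OLFML3 (4.71). The any-time count was 67 without DBDmut 24 h A and 688 without WT 24 h B.

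With all arrays few genes were called in both lines at the same time. These were GADD45A at 2 h, a growth arrest gene that changed by -1.40 in WT and 1.34 in DBDmut, ARRB1 at 8 h (1.27 and 1.20), and at 24 h PRSS3 (-0.95 and -0.52) and BMERB1 (1.22 and -1.05), so that GADD45A and BMERB1 went in opposite directions. Across the 5575 genes, which are not independent replicates, Pearson's r between the log2 changes of WT and DBDmut was -0.354, 0.0391, 0.0269, 0.00922 and -0.0731 at 1, 2, 4, 8 and 24 h. Spearman's rho was -0.407, -0.0204, -0.0328, -0.0373 and -0.109. Without the array labelled WT 24 h A, 14 genes rose in both lines at 8 h against 2.94 for independent lists, 10 fell in both against 1.39, and 12 changed in opposite directions against 4.05. At 24 h these were 23 against 4.12, 9 against 1.47 and 18 against 5.04. Calls in both lines share the estimate of a gene's spread, so genes with a small spread tend to be called in both. Counts above those for independent lists may come from this, in either direction. Changes in the same direction at 8 h included RHOB (1.65 in WT and 4.68 in DBDmut), HEG1 (1.59 and 3.62) and PITX1 (3.67 and 1.71). At 4 h in that setting the opposite changes included EGR1 (1.71 in WT and -1.33 in DBDmut), ZMIZ1 (2.49 and -1.65) and PLAU (-1.18 and 1.41). The value at 1 h moved to 0.0464 without the array labelled WT 1 h A.

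Before E2, SH3BGRL, CCL2 and IFI44 were among the genes higher in WT, and HCLS1, TIE1 and KISS1 among those higher in DBDmut. SH3BGRL was lower in DBDmut, at -5.79 ± 1.14 (DBDmut minus WT, SE, adjusted p = 0.00643), CCL2 at -5.52 ± 0.90 and the interferon-induced IFI44 at -5.48 ± 0.94. In DBDmut SH3BGRL and IFI44 averaged 2.82 and 2.79 over all times, under the median value of every array, so their sizes are imprecise. HCLS1, an adaptor protein of blood cells, was higher in DBDmut by 5.37 ± 1.02 (adjusted p = 0.00534), the endothelial receptor kinase TIE1 by 3.93 ± 0.78 and the metastasis suppressor KISS1 by 3.80 ± 0.77. Also lower in DBDmut were the near-identical cystatins CST4 (-5.21) and CST1 (-4.46), TCN1 (-4.70), the histone gene H2AC6 (-4.48), which shares sequence with other histone genes, TSPYL1 (-4.25), IFIT2 (-4.05) and OASL (-3.90). TCN1, H2AC6 and TSPYL1 averaged 2.48, 2.48 and 2.55 in DBDmut over all times, again under the median value of every array. Also higher were SERPINF1 (2.98), the cortisol-activating enzyme gene HSD11B1 (2.73), DDIT4 (2.27), DGAT1 (2.23), FARP1 (2.21), IL11 (2.16) and RAB20 (1.96). Interferon response genes were lower in DBDmut as a list (median -1.19, camera adjusted p = 5.1e-04, adjusted p = 0.366 with an estimated correlation). Of these, 8 of 17 members were called higher in WT and 0 in DBDmut, or 14 and 1 without the array labelled WT 24 h A. TGF-beta pathway genes were lower too (median -0.60, adjusted p = 0.0148, adjusted p = 0.366 with an estimated correlation, 4 of 14 higher in WT, or 7 without that array). In all 976 genes differed, 201 higher in DBDmut and 775 higher in WT, where the median over all tested genes was -0.15. Quantile normalization moved this median to -0.00224 and the split to 328 and 590. The count was 1528 (374 and 1154) without the array labelled WT 24 h A. It was 4 without DBDmut 0 h A2, though 81 genes against 95 then still differed by more than 2 log2 units, and 733 without both arrays.

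The remaining lists gave few calls in the time courses with all arrays. RUNX factors and partners (4 tested members) had no list call, and of them TLE3 (1.41 at 4 h) rose and TLE1 (-1.11) fell in DBDmut, with 0 called by limma in WT (2 at an unadjusted p under 0.05). TLE3 rose in both lines without the array labelled WT 24 h A, at 8 h (1.37 in WT and 0.96 in DBDmut). Cholesterol and fatty acid synthesis genes (20 members) had no list call and 0 members called by limma in either line (2 in WT and 1 in DBDmut at an unadjusted p under 0.05, 0 adjusted over the list alone). Unfolded protein and amino acid response genes went up in WT at 24 h (median 0.07, camera adjusted p = 0.0207, adjusted p = 0.170 with an estimated correlation), a call lost without the array labelled WT 24 h A (adjusted p = 0.114). CEBPB and DDIT4 were called among 23 members (2 adjusted over the list alone). DDIT4, higher in DBDmut at 0 h, had its largest change in WT at 24 h (1.48) with all arrays and at 2 h (-1.29) without that array. Hypoxia and glycolysis genes went up at 24 h too (median 0.06, adjusted p = 0.0426, adjusted p = 0.331 with an estimated correlation), and VEGFA rose and ADM fell among 17 (2 adjusted over the list alone). Interferon response genes had a median of -0.56 in WT at 24 h with all arrays (adjusted p = 0.0157, adjusted p = 0.647 with an estimated correlation). It was -0.15 without the array labelled WT 24 h A, where camera, which compares the list with the other genes, gave the direction up (adjusted p = 0.291). Of 17 members 0 were called by limma in either line (2 in WT and 0 in DBDmut at an unadjusted p under 0.05), and ISG20, IRF7 and IRF9 rose in WT without that array. Mesenchymal genes (12 members) had no list call with all arrays, with a rise of NNMT and falls of AXL (-0.94) and VIM (-0.36) in DBDmut (4 adjusted over the list alone) and 0 called by limma in WT (1 at an unadjusted p under 0.05). They went up in WT at 24 h without that array (adjusted p = 0.0260, adjusted p = 0.222 with an estimated correlation), with 1 rise called. Markers of luminal breast lines (3 tested) and of fibroblasts (3 tested), fixed as signs of other cell types, had no list call and 0 members called by limma in either time course with all arrays (1 and 0 in WT and 1 and 1 in DBDmut at an unadjusted p under 0.05). Without that array 1 fibroblast marker, COL6A3, rose in DBDmut (1.37 at 8 h) and 1 differed in response, and at 0 h 2 fibroblast markers and 1 luminal marker were higher in DBDmut.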

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

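The tests on the array labelled WT 24 h A and on glucocorticoid response genes were chosen after the results were seen, as was the setting without that array. Those on the 1 h changes were written down before their outcomes were seen, but with the pattern and the arrays they name in view.

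The array labelled WT 24 h A lay with the arrays of the DBDmut line. An exchange with an array labelled DBDmut among these samples is argued against, since the lowest position of those arrays was 0.914. So is a mixture with 10% or more of WT RNA, for which the median share over 261 genes was 0.320% (95% bounds -0.225 and 1.18). Those bounds take genes of 1 array as independent, so they may be too narrow. An exchange with an array not among these samples was not tested, and the title A2 of a DBDmut 0 h array is not explained by the labels. A first form of that test, on genes at 9 or more in WT, left 0 genes, and at 7 or more 3 genes with a median of 2.72 on the array. RNA of the DBDmut line under a WT label is consistent with its position of 0.957, inside the range of the DBDmut arrays, and by correlation its nearest group mean was DBDmut 0 h. At which step such a mix-up may have occurred stays open, and no biological explanation was tested.

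The log2 changes at 1 h ran in opposite directions in the lines across genes (r = -0.354). Without both arrays WT 1 h A and DBDmut 0 h A2, r was 0.0342, against 0.0464 without WT 1 h A and -0.172 without DBDmut 0 h A2. A deviation shared by them may give this, but they were named with the pattern in view, so the test cannot decide it. Opposite responses stay open and cannot be told apart from chance here. The interval given next takes genes as independent, though they share the same few arrays. Without the array labelled WT 24 h A, 48.3% of 29 genes called at 1 h in either line had opposite signs (exact 95% interval 29.4 to 67.5).

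Glucocorticoid response genes went up as a list at 24 h in DBDmut and WT (camera adjusted p = 2.0e-07 and 0.0118, adjusted p = 0.124 and 0.419 with an estimated correlation, or 0.0213 and 0.0180 without the array labelled WT 24 h A). Medium or time in culture stays open, since no later array without E2 exists and the lines may answer the same medium differently. Random draws of 12 genes give up to 2 that differ between lines in 95% of draws, though members of a list are not independent. Without WT 24 h A, 6 of 12 members had a response that differed between lines, which argues only against an equal response of both lines. At its largest difference (WT minus DBDmut) each gave FKBP5 -2.79 at 24 h, TSC22D3 -1.65 at 4 h, DUSP1 -2.09 at 8 h, MT1X -0.48 at 24 h, NFKBIA 1.07 at 1 h and CRISPLD2 3.54 at 24 h. Action of the mutant receptor on glucocorticoid-type elements may contribute but cannot be told apart from other differences between the lines, since the list's difference at 24 h had an adjusted p of 0.348 without that array and 0.0183 with it. A difference between the lines in their use of the hydrocortisone in the medium was not tested.

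By the test of the interaction, 114 genes responded differently in the lines at any time, 47 at 8 h and 99 at 24 h. These values are from all arrays, so the WT 24 h group includes the array labelled WT 24 h A. Named genes with the higher change in WT were ZMIZ1 (4.34 at 8 h), TRIB2 (4.25 at 24 h), MMP1 (3.97 at 24 h), MXD1 (3.28 at 2 h), EGR1 (3.03 at 4 h), SERPIND1 (2.79 at 24 h), STS (2.71 at 24 h), ACOX2 (2.66 at 24 h), IER3 (2.64 at 8 h) and P3H2 (2.63 at 24 h). Those with the higher change in DBDmut were TGFBI (-7.78 at 24 h), PLAT (-6.48 at 24 h), SLC26A2 (-6.45 at 24 h), CXCL8 (-5.84 at 24 h), AKR1C1 (-4.36 at 24 h), AKAP12 (-4.35 at 8 h), TNFAIP3 (-4.32 at 24 h), AKR1C2 (-4.12 at 24 h), SHROOM2 (-4.05 at 4 h) and PTGES (-3.80 at 8 h). Without the array labelled WT 24 h A the same rule was led toward WT by TFF1 (6.88), SERPINA1 (5.06) and OLFML3 (4.71), all at 24 h. Toward DBDmut it was led by TGFBI (-7.07), SLC26A2 (-5.42) and PLAT (-5.41), also at 24 h. The WT 24 h group is then 1 array. Of the lists, TGF-beta pathway genes differed at 2 and 4 h (camera adjusted p = 0.00966 and 0.0443, adjusted p = 0.891 and 0.891 with an estimated correlation), and ribosome biogenesis genes at 4 and 8 h (adjusted p = 0.0231 and 3.0e-05, adjusted p = 0.891 and 0.891 with an estimated correlation). Classical oestrogen-induced, DNA replication and NF-kB genes differed at 8 h (adjusted p = 0.00523, 3.4e-04 and 0.0203, adjusted p = 0.571, 0.891 and 0.891 with an estimated correlation). NF-kB, AP-1 linked protease and glucocorticoid response genes differed at 24 h (adjusted p = 0.0181, 0.00665 and 0.0183, adjusted p = 0.891, 0.237 and 0.891 with an estimated correlation). The adjusted p was, without the array labelled WT 24 h A, 0.0815 for TGF-beta pathway genes at 4 h and 0.0820 for NF-kB genes at 24 h, and for ribosome biogenesis genes adjusted p = 0.0147 with an estimated correlation at 8 h.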

How the results depend on the processing

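The settings that leave out 2 or 3 named arrays were chosen after the arrays were seen. Of the named genes' results and list calls, those under quantile normalization kept their direction, and 117 gene results and 44 of 49 list calls kept their side of the threshold. With all arrays and an estimated correlation 1 of 49 list calls stayed past the threshold, and with fry 11. Of the list calls at 0 h, fry kept 2 of 2. Without the array labelled WT 24 h A, more list calls of both time courses and of the response difference stayed past it under either method. The cause was not tested except where stated. Genes called were, with quantile normalization, 83 (at any time), 15 (4 h) and 57 (8 h) in WT. There the line difference was 328 higher and 590 lower, and the response difference 27 higher and 33 lower at 8 h and 63 higher and 63 lower at 24 h, against 14 and 33, and 38 and 61, as deposited. They were, with each probe set on its own, which tests more features, 81 (at any time), 26 (2 h), 16 (4 h), 34 (8 h) and 15 (24 h) in WT. There were 234 (24 h) in DBDmut. With no filter, which tests more genes, there were 5 (1 h), 14 (4 h) and 12 (24 h) in WT. There were 3 (1 h) in DBDmut. There were 30 (8 h) for the response difference. With the stricter filter there were 31 (8 h) in WT. With the mean of probe sets there were 41 (8 h) and 12 (24 h) in WT. There were 4 (1 h) in DBDmut. With a replicate block, which takes the letters as pairing, there were 98 (at any time), 5 (1 h), 19 (4 h), 85 (8 h) and 12 (24 h) in WT. There were 77 (8 h) and 165 (24 h) for the response difference. Residuals of arrays with one letter correlated above 0.1 in 54 of 66 pairs of groups and under -0.1 in 5. With the 12 arrays of the line alone, limma called 0 genes in WT at any time (250 at an unadjusted p under 0.05) and 0 at 1, 2, 4, 8 and 24 h (160, 92, 151, 386 and 347 unadjusted). DBDmut counts were 239 (at any time), 26 (1 h), 43 (2 h), 133 (4 h), 170 (8 h), 286 (24 h). Fewer arrays give fewer degrees of freedom, but the DBDmut any-time count rose from 150 to 239, so this alone does not give the 0 in WT. The WT arrays include WT 24 h A. The SD over genes of the difference within a pair was 0.874 for WT 24 h and 0.701 for WT 1 h. It lay between 0.252 and 0.381 for the other groups of both lines. Without WT 24 h A and WT 1 h A there were 421 (at any time), 6 (1 h), 65 (2 h), 122 (4 h), 432 (8 h) and 376 (24 h) in WT. There were 332 (at any time), 29 (1 h), 55 (2 h), 174 (4 h), 230 (8 h) and 392 (24 h) in DBDmut. There were 347 (at any time), 344 (8 h) and 410 (24 h) for the response difference. There were 1992 (0 h) for the line difference. Without DBDmut 0 h A2 as well there were 477 (at any time), 8 (1 h), 71 (2 h), 140 (4 h), 506 (8 h) and 425 (24 h) in WT. There were 327 (at any time), 39 (2 h), 129 (4 h) and 162 (8 h) in DBDmut. There were 343 (at any time), 238 (8 h) and 312 (24 h) for the response difference. The line difference was 3356 averaged over 6 times, with more arrays, and 1628 without WT 24 h A and DBDmut 0 h B, but 733 without WT 24 h A and DBDmut 0 h A2. The median absolute t of genes that differed by more than 2 log2 units was 4.64 with all arrays, 8.99 without WT 24 h A and 3.71 without A2. Leaving out 1 array at a time, the lone partner is assumed to vary like other groups. Without WT 24 h B the WT 24 h group is WT 24 h A alone. The any-time and 24 h counts of WT and of the response difference then also hold the difference between the lines. WT at any time ranged from 4 (WT 0 h A) to 978 (WT 24 h B). DBDmut at any time ranged from 96 (DBDmut 24 h B) to 234 (WT 24 h A). WT 1 h ranged from 1 (WT 0 h A) to 1283 (WT 1 h B). WT 2 h ranged from 3 (WT 2 h A) to 51 (WT 24 h A). WT 4 h ranged from 0 (WT 0 h B) to 71 (WT 24 h A). WT 8 h ranged from 0 (WT 0 h A) to 294 (WT 24 h B). WT 24 h ranged from 0 (WT 0 h A) to 794 (WT 24 h B). DBDmut 1 h ranged from 2 (DBDmut 0 h A2) to 24 (DBDmut 0 h B). DBDmut 2 h ranged from 11 (DBDmut 0 h A2) to 45 (WT 24 h A). DBDmut 4 h ranged from 30 (DBDmut 4 h A) to 123 (WT 24 h A). DBDmut 8 h ranged from 48 (DBDmut 8 h A) to 160 (WT 24 h A). DBDmut 24 h ranged from 88 (DBDmut 24 h A) to 244 (WT 24 h A). Difference at any time ranged from 67 (DBDmut 24 h A) to 688 (WT 24 h B). Difference 8 h ranged from 15 (WT 0 h B) to 224 (WT 24 h A). Difference 24 h ranged from 54 (WT 0 h B) to 713 (WT 24 h B). Line difference 0 h ranged from 4 (DBDmut 0 h A2) to 1528 (WT 24 h A). The lowest counts of 0 had 138, 520 and 451 genes at an unadjusted p under 0.05. Correlations between lines ranged over -0.425 to 0.0464 at 1 h, -0.0680 to 0.175 at 2 h, -0.0172 to 0.0733 at 4 h, -0.0320 to 0.0614 at 8 h, -0.104 to 0.0171 at 24 h. The 24 h changes in WT of 8 genes had opposite signs without WT 24 h A and without B. Without B the group is WT 24 h A alone, which lay with the DBDmut arrays, so the change then also holds the difference between the lines. The turn of sign therefore cannot test the response of these genes in WT. Without A every 24 h value of WT rests on WT 24 h B alone. The rises without A ranged over TFF1 -2.48 to 6.95, TGM2 -0.059 to 4.43, INHBB -0.80 to 3.68, C3 -2.86 to 3.48, CST1 -4.69 to 3.43. The falls ranged over NDC1 -1.62 to 0.33, TWNK -1.57 to 0.18, PLAU -1.57 to 0.62, and the TFF1 difference over -2.55 to 6.88. CST1 was 3.43 without WT 24 h A in each such setting. Directions of lists in camera turned for mitosis genes in WT at 8 h without WT 8 h A (adjusted p range 3.9e-08 to 0.574) and for interferon genes at 24 h without WT 24 h A (0.291, range 1.5e-08 to 0.291). They turned for DNA replication (0.142, range 2.3e-10 to 0.142) and glucocorticoid response genes (0.876, range 9.0e-07 to 0.876) at 24 h without WT 24 h B. Signal over background limits weak genes, since 5575 of 11963 genes passed the filter.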

Other observations

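The setting without the array labelled WT 24 h A was chosen after its position was seen.

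Without that array FOSL2, a FOS family member, rose in both lines (1.86 in WT and 1.44 in DBDmut at 8 h), while FOSL1, another, fell in both (-0.99 and -1.47 at 4 h). DUSP6, a phosphatase of ERK, changed by -1.02 in WT and 1.49 in DBDmut at 2 h (adjusted p of the difference = 1.2e-04). BMP4, a growth factor of the TGF-beta family, rose in WT by 2.79 ± 0.30 at 8 h (adjusted p = 2.2e-05). The cell cycle inhibitor gene CDKN1A rose in WT by 1.33 ± 0.22 at 8 h, and its response differed between the lines by 2.06 ± 0.32 (adjusted p = 1.0e-03). These genes were chosen after their values were seen.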
